A study of Mus musculus with 8 samples.

How the data were processed

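Whole mouse corneas of 2 genotypes, 4 Opn5-null and 4 wild-type, were collected 12 hours after epithelial debridement and their total RNA was sequenced. Per the labels' protocols, ribosomal and globin RNA was depleted and libraries were made with a stranded kit. Per the submitters' processing notes, RSEM 1.3.1 was used. The aligner, genome build, annotation and strand setting are not given in the sources used here.

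The deposited table held 1 signal value per gene and library, which the values show to be gene counts divided by 1 size factor per library. Whole reads were recovered by dividing each column by its smallest nonzero value, and 100% of values came out whole within 0.001. Totals ranged from 21111715 to 28219234 reads per library, and the lowest total of any gene over the 8 libraries was 81 reads. The authors' deposited log2 fold changes and p-values, per the file headers, came from their own comparison of the genotypes. The authors' deposited table called 3516 genes higher and 2716 lower at an adjusted p-value below 0.05, over 16082 genes with a p-value. All 8 sample titles hold the word Light, and no label used here explains it. Strain, the details of any light exposure and time of day at collection are not given in the sources used here.

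Because the table held normalized values rather than counts, the main test was limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance estimation, on log2(value + 1). Genes with a value of at least 1 in 4 or more libraries were kept, which left 16085 of 16091. A fold change is on the log2(value + 1) scale, which understates the change of low genes, and folds in the text are ratios of mean normalized counts. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Sample letters were not used as a block. Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 over 40 lists with 5 or more measured members. Beside it stood camera with an estimated correlation, with which 0 lists passed, and fry, whose p tests whether members move one way on balance.

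Named genes followed a rule fixed before the data were examined. It took the 10 largest changes per direction among called genes with a mean of at least 1 in the higher group, all 4 libraries of one genotype beyond the other, and a symbol other than a predicted-gene code. It also took the 5 lowest p per direction and, in each list, up to 4 called members, or 2 where none was called. Some genes that met the rule are not reported here, though they were kept in the tests and lists. The targeted gene Opn5 came first in the rule and was not analysed here. For genes with 3 or fewer reads in a group the ratio has an exact binomial 95% interval, which covers counting error only. Of the gene identifiers, 16055 of 16091 matched GENCODE M21 (GRCm38), from which chromosomes and gene types were taken. Parents of processed pseudogenes were their best matches among coding transcripts with BLAST+ 2.17.0.

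Alternatives were quantile normalization, upper-quartile scaling, no filter, a filter at 1 CPM in 4 libraries, a block by letter, each library left out, a pseudocount of 0.1, other thresholds, limma-voom with quality weights and DESeq2 1.42.0 on recovered reads. Added after seeing the data were edgeR 4.0.16 on recovered reads, TMM scaling in the limma fit, and leaving out both libraries lettered D. The edgeR quasi-likelihood test called 3004 genes higher and 2045 lower of 15936. In every pair of libraries of a genotype the counts differed by more than sampling noise, with chi-square values per gene from 10.4 to 199. The limma step was tested on simulated data for this comparison with 16090 genes run. It recovered 19.4% of 67 genes changed 1.5-fold, 53.7% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, and called 8 unchanged genes. Far fewer genes were changed there than were called in the data, so these rates need not hold for the data.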

Results

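Mouse corneas lacking Opn5, the gene for the violet- and ultraviolet-sensitive photopigment opsin 5 (neuropsin), were compared with wild-type corneas after removal of the epithelium. There were 4 Opn5-null and 4 wild-type samples, each collected 12 hours after debridement. Bulk RNA was measured in whole corneas, so that epithelium, stroma, endothelium and infiltrating cells contributed together. The deposited table held normalized counts for 16091 genes. Recovered reads per library ranged from 21111715 in Opn5-null B to 28219234 in Opn5-null D. No label stated that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The targeted gene, Opn5, on chromosome 17, was not analysed here, and the genotypes rest on the labels alone.

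The comparison asked how the transcripts of the wounded cornea differ without Opn5. Lists of interferon-stimulated genes, inflammatory cytokines and chemokines, and leukocyte markers were higher in Opn5-null corneas by camera with a preset correlation. Their calls were lost with an estimated correlation, with adjusted p = 0.48 to 0.49. Lists of cholesterol biosynthesis genes, S phase genes and markers of differentiated corneal epithelium were lower by the same test. With an estimated correlation they had adjusted p = 0.51, 0.48 and 0.62, and the epithelial list, with 9 of 33 markers lower, also missed the threshold with fry (adjusted p = 0.0999). Of 16085 genes tested with limma, 3029 were higher and 2175 were lower in Opn5-null corneas at a Benjamini-Hochberg adjusted p below 0.05. Among them, 1770 were higher and 670 were lower by at least 1 on the log2 scale. The first principal component held 72.6% of the variance and parted the genotypes. In 4876 of the called genes all 4 libraries of one genotype lay beyond all 4 of the other. Over all genes tested, 38.4% showed such a separation, against 2.86% by chance. The share of calls that were higher was 58.2% with the deposited scaling, 40.3% after quantile normalization and 40.8% with upper-quartile scaling. Those scalings placed the median log2 fold change of all genes at -0.13, against -0.02 with the deposited one. The count of lower genes was 1078 without wild-type A, 1242 without wild-type C and 1288 without wild-type D.

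**Figure D1:**
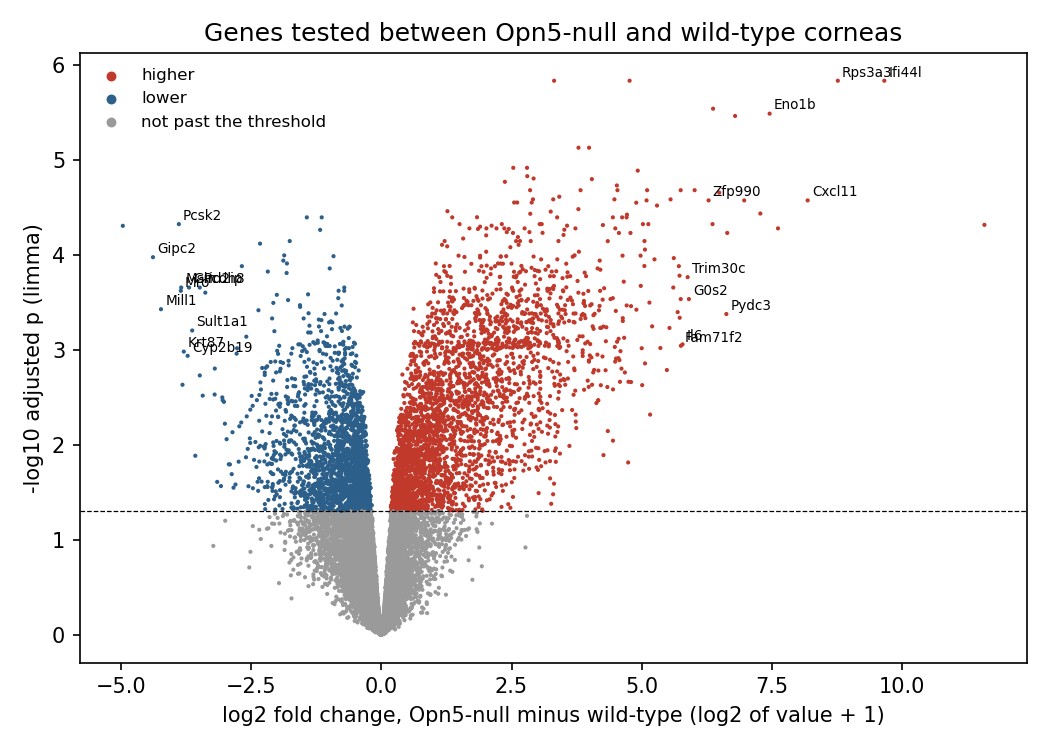
Each point is 1 gene, with the log2 fold change of Opn5-null against wild-type corneas on the horizontal axis and -log10 of the limma adjusted p on the vertical axis. Red points are the 3029 higher genes, blue points the 2175 lower genes, and the named genes are those with the largest changes under the naming rule.

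Ifi44l, an interferon-induced gene on chromosome 3 (ENSMUSG00000039146), had the largest log2 fold change among the named genes, 9.66 ± 0.29 (SE, adjusted p = 1.48e-06 by limma). It measured 971 ± 237 normalized counts in Opn5-null corneas and 0.230 ± 0.459 in wild-type corneas (SD, n = 4). Only 1 read was recovered in the wild-type group, in wild-type B, against 3703 in the Opn5-null group, a ratio of 3920 with a 95% counting interval from 704 to 155000. No label gives the strain, so the near absence of Ifi44l, or of another named gene, from 1 genotype cannot be told apart from a strain difference. The chemokine gene Cxcl11, annotated as a polymorphic pseudogene in GENCODE M21, was higher by 8.19 ± 0.47 (SE). Il6, which encodes interleukin 6, was 47.9-fold higher, with 1656 ± 977 against 34.6 ± 28.7 normalized counts (SD, n = 4). G0s2, an inhibitor of triglyceride lipase, was 63.6-fold higher, and 95.7-fold without wild-type B. Pydc3 and Trim30c, members of interferon-inducible families, were higher by 6.63 and 5.88 on the log2 scale. Fam71f2 and the zinc finger gene Zfp990 were higher by 5.75 and 6.28, and Fam71f2 by 6.38 without Opn5-null C. With 2 reads in the wild-type group, Zfp990 had a ratio of 239, with a 95% counting interval from 65.8 to 1980. Its ratio of mean counts was 358 without wild-type C, against 236. Rps3a3 and Eno1b, close relatives of the genes Rps3a1 and Eno1, were higher by 8.76 and 7.46. Reads can be shared between such near-identical copies, so the levels of Rps3a3, Eno1b, Pydc3 and Trim30c are uncertain. Among the 5 genes with the lowest p in the higher direction, Ifi44l stood beside the pseudogenes Rps26-ps1, Gm4735, Rps3a3 and Gm8730. Genes with predicted-gene codes or pseudogene names made up 348 of the higher calls and 197 of the lower calls.

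Gipc2 on chromosome 3 was lower in Opn5-null corneas, with a log2 fold change of -4.38 ± 0.35 (SE, adjusted p = 0.000106 by limma). Its level was 21.6 ± 13.4 normalized counts in Opn5-null and 421 ± 41.6 in wild-type corneas (SD, n = 4). Msln, which encodes mesothelin, was 13.3-fold lower, and Pcsk2, a prohormone convertase gene, was 17.9-fold lower. Mill1, an MHC class I-like gene, had a log2 fold change of -4.23, and Mro of -3.85. With 3 reads in the Opn5-null group, Mro was lower by a ratio of 30.5, with a 95% counting interval from 10.1 to 151. The keratin gene Krt87 and the cytochrome P450 gene Cyp2b19 had log2 fold changes of -3.79 and -3.72. Grid2ip, the sulfotransferase gene Sult1a1 and the protocadherin gene Pcdh8 had log2 fold changes of -3.69, -3.63 and -3.49. The lowest p among lower genes belonged to Ahcy, A430105I19Rik, Pcsk2, Gm10375 and Gss. Gm10375 had the lowest log2 fold change among the named genes, -4.96, and with 1 read in the Opn5-null group, in Opn5-null C, its ratio was 141, with a 95% counting interval from 24.9 to 5590. Ahcy, which encodes adenosylhomocysteinase, fell by 1.14 on the log2 scale, and Gss, which encodes glutathione synthetase, fell by 1.17.

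Interferon-stimulated genes were higher as a group. All 36 of the members tested rose (36 adjusted over the list alone), with a median log2 fold change of 2.71 (camera adjusted p = 6.19e-27). With an estimated correlation the adjusted p = 0.48. Zbp1, a sensor of Z-form nucleic acids, was 15.9-fold higher, and Oas1a, an oligoadenylate synthetase gene, 7.08-fold higher. Ifi27l2a and Ifi44 were higher by 4.04 and 3.83 on the log2 scale. Among inflammatory cytokines and chemokines, 31 of 35 rose and 1 fell (31 and 1 adjusted over the list alone), with a median log2 fold change of 3.39 (camera adjusted p = 6.21e-15). That list had adjusted p = 0.48 with an estimated correlation. Among Opn5-null libraries it was highest in A at 3.92 and lowest in C at 2.30, as log2 differences from the wild-type mean, and the dissociation and ischaemia stress list was highest in A at 1.69 and lowest in C at 0.36. The interferon-stimulated list was highest in D at 3.46 and lowest in C at 2.55. Cxcl10, a chemokine for activated T cells, measured 4315 ± 3360 against 76.1 ± 42.2 normalized counts (SD, n = 4), a ratio of 56.7, and of 34.8 without Opn5-null D. Cxcl5, a neutrophil-attracting chemokine gene, was 20.3-fold higher, Ccl7 10.9-fold higher and Ccl8 7.33-fold higher. Antigen presentation genes of MHC class I and II rose in 16 of 21 cases and fell in 0 (17 adjusted over the list alone). Their camera adjusted p = 2.83e-12, and their adjusted p = 0.48 with an estimated correlation. Tap1, a peptide transporter gene, and Psmb9, an immunoproteasome subunit gene, were higher by 1.90 and 2.31 on the log2 scale. H2-T22 and H2-T23, members of a multigene family whose reads can be shared, were higher by 1.27 and 1.26.

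Leukocyte markers rose together with these genes. Of 26 neutrophil markers tested, 21 rose and 1 fell (22 and 2 adjusted over the list alone), with a median log2 fold change of 2.60 (camera adjusted p = 6.86e-09). The neutrophil list had adjusted p = 0.49 with an estimated correlation. Acod1, the gene of the itaconate-producing enzyme, was 44.5-fold higher, and 75.3-fold without wild-type B. The receptor genes Trem1 and Clec4e were higher by 4.66 and 4.08 on the log2 scale. Monocyte and macrophage markers rose in 16 of 22 cases and fell in 1 (16 and 1 adjusted over the list alone). Their camera adjusted p = 4.57e-08, and with an estimated correlation the adjusted p = 0.48. The Fc receptor gene Fcgr1 was 14.2-fold higher, the chemokine receptor gene Ccr2 5.39-fold and Ly6c2 23.7-fold. Dendritic cell and lymphocyte markers rose in 15 of 25 cases and fell in 0 (16 and 1 adjusted over the list alone), with camera adjusted p = 6.72e-06 and adjusted p = 0.48 with an estimated correlation. Gzma, which encodes granzyme A, was 16.4-fold higher, and Itgax, the gene of the integrin CD11c, was 10.2-fold higher.

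**Figure D2:**
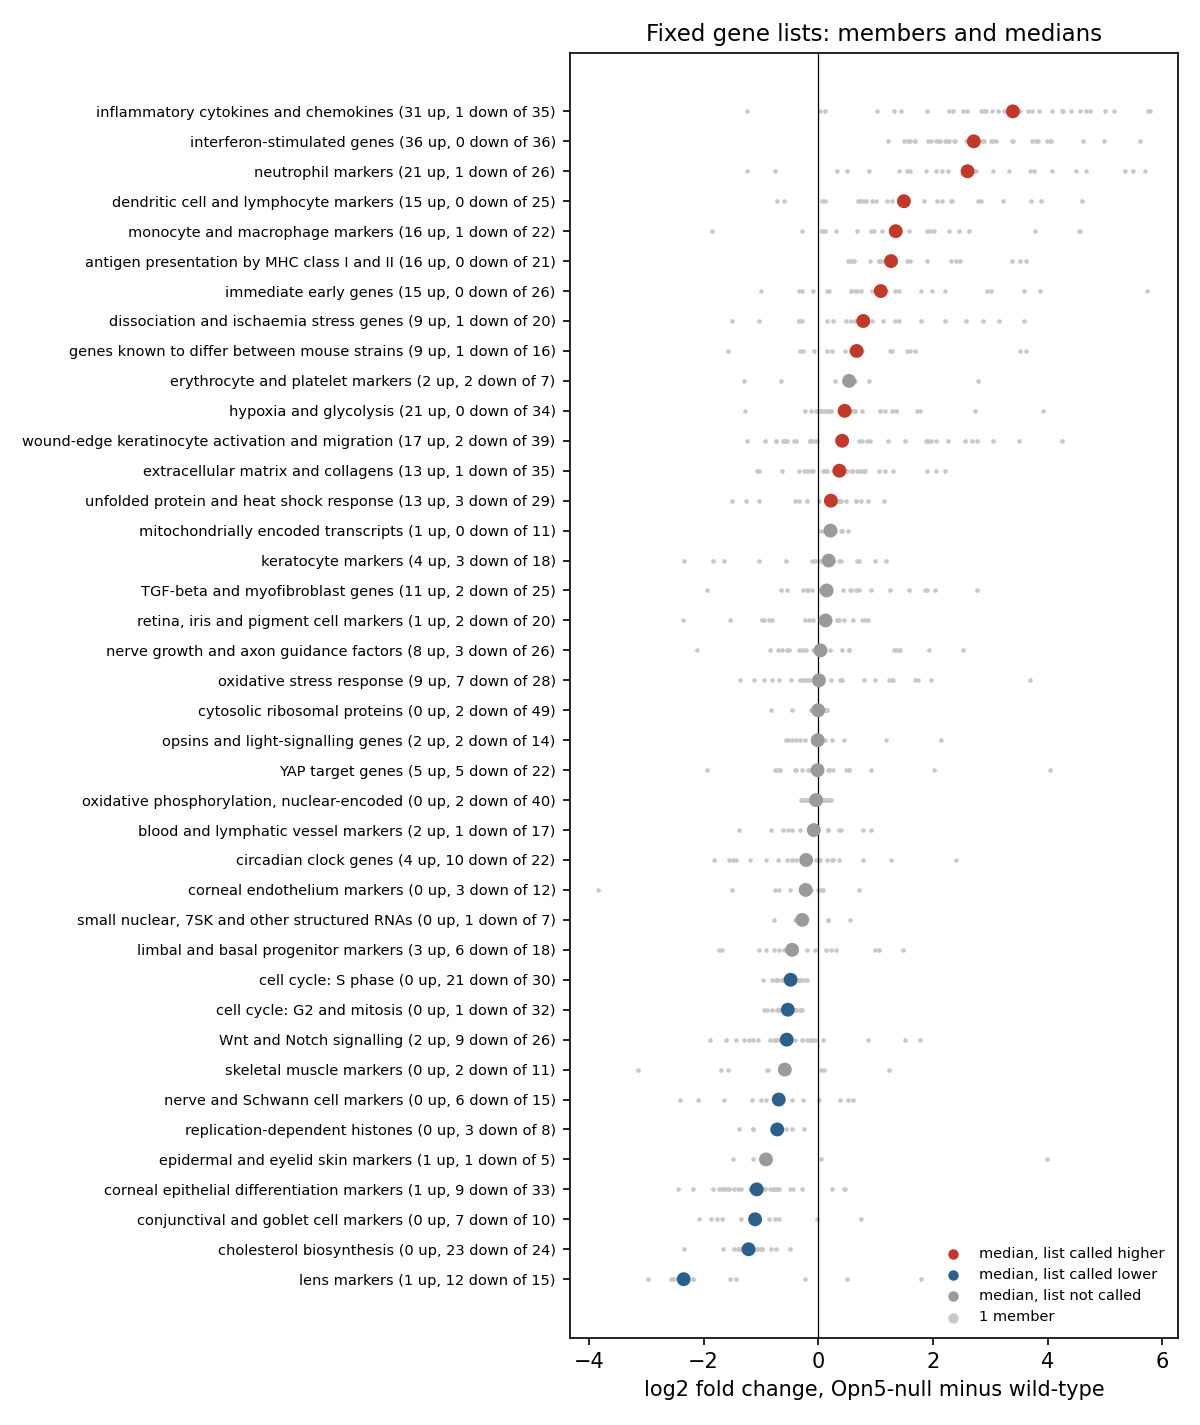
Small grey points are the log2 fold changes of single members of each fixed gene list, Opn5-null against wild-type, and large points are list medians, coloured by the camera call. Inflammatory cytokines and chemokines had the highest median, 3.39, and lens markers the lowest, -2.35.

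Wound-edge keratinocyte activation and migration genes rose in 17 of 39 cases and fell in 2 (17 and 2 adjusted over the list alone). Mmp3 measured 141200 ± 29570 normalized counts in Opn5-null and 23830 ± 2495 in wild-type corneas (SD, n = 4). Mmp10 was 19.9-fold higher, Mmp1b 11.5-fold and Mmp9 8.60-fold. The wound-edge list had camera adjusted p = 0.0127, adjusted p = 0.67 with an estimated correlation. Its adjusted p was 0.143 without Opn5-null A and 0.216 with genes shared between lists left out, which ended the call. Of its members 6 fell without Opn5-null A and 4 without Opn5-null D, and its median was 0.23 without Opn5-null A, against 0.42. Immediate early genes rose in 15 of 26 cases and fell in 0 (16 adjusted over the list alone), with camera adjusted p = 4.77e-05 and adjusted p = 0.55 with an estimated correlation. The nuclear receptor genes Nr4a3 and Nr4a1 were 60.9-fold and 14.3-fold higher, and 37.5-fold and 9.06-fold without Opn5-null A. The phosphatase gene Dusp2 was 16.1-fold higher. Extracellular matrix and collagen genes rose in 13 of 35 cases and fell in 1 (16 and 3 adjusted over the list alone), with camera adjusted p = 0.00562 and adjusted p = 0.51 with an estimated correlation. Of these genes 4 fell without Opn5-null D, 2 without Opn5-null C and 0 without each wild-type library in turn. Col3a1 and Tnc, which encodes tenascin C, were higher by 1.90 and 2.06 on the log2 scale. Hypoxia and glycolysis genes rose in 21 of 34 cases and fell in 0 (22 adjusted over the list alone), with camera adjusted p = 1.24e-06 and adjusted p = 0.48 with an estimated correlation. Slc16a3, a lactate transporter gene, was 15.6-fold higher, and the glucose transporter gene Slc2a1 2.59-fold higher. Unfolded protein and heat shock genes rose in 13 of 29 cases and fell in 3 (14 and 4 adjusted over the list alone), with camera adjusted p = 0.0127 and adjusted p = 0.67 with an estimated correlation. Their call ended after quantile normalization, with adjusted p = 0.103, and in the edgeR fit, with adjusted p = 0.158. The count that rose was 8, 7 and 8 without Opn5-null A, wild-type A and wild-type C, and the count that fell was 1 without each wild-type library in turn. The transcription factor gene Ddit3 was higher by 1.15, and Chac1 fell by 1.26 on the log2 scale. Dissociation and ischaemia stress genes, fixed as a sign of tissue handling, rose in 9 of 20 cases and fell in 1 (9 and 2 adjusted over the list alone). Their camera adjusted p = 0.0106, with adjusted p = 0.67 with an estimated correlation and 0.0523 with fry. Many of these genes, Fos, Jun, Egr1 and Nr4a1 among them, are also in the immediate early list, so the rises of these lists are not separate results. With genes shared between lists left out, the stress list had too few members to be tested, while the immediate early list still passed. Gadd45b was 9.64-fold and Socs3 7.71-fold higher.

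Cholesterol biosynthesis genes were lower in Opn5-null corneas, with 23 of 24 members falling and 0 rising (24 and 0 adjusted over the list alone). Their median log2 fold change was -1.22 (camera adjusted p = 4.29e-09), and with an estimated correlation the adjusted p = 0.51. Lss, the lanosterol synthase gene, was 2.93-fold lower, Hsd17b7 1.94-fold lower and the sterol sensor gene Insig1 2.54-fold lower. Corneal epithelial differentiation markers fell in 9 of 33 cases and rose in 1 (8 and 1 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 7.61e-05). The epithelial list had adjusted p = 0.62 with an estimated correlation and 0.0999 with fry. Aldh1a1, a corneal aldehyde dehydrogenase gene, was 3.27-fold lower and the mucin gene Muc16 2.94-fold lower, while the connexin gene Gja1 was 1.36-fold higher, a call that ended after quantile normalization (adjusted p = 0.107). The mean level of the epithelial list was -2.33 in Opn5-null D and between -0.89 and -0.48 in the other Opn5-null libraries, as log2 differences from the wild-type mean. Without Opn5-null D, 17 epithelial markers fell and the median was -0.63, and 4 fell without each wild-type library in turn. The cholesterol list stood at -2.16 in Opn5-null D, and without that library 24 members fell with a median of -0.89. Without wild-type A, B and C in turn, 13, 14 and 13 cholesterol genes fell.

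S phase genes fell in 21 of 30 cases and rose in 0 (25 and 0 adjusted over the list alone), with camera adjusted p = 3.18e-09 and adjusted p = 0.48 with an estimated correlation. Without wild-type A, 13 S phase genes fell. Uhrf1 and Chaf1b were 1.65-fold and 1.53-fold lower. Pcna was 1.65-fold lower, but its near-identical copy Pcna-ps2 was higher by 3.79 on the log2 scale, and reads can be shared between them. G2 and mitosis genes fell in 1 of 32 cases and rose in 0 (0 and 0 adjusted over the list alone), with camera adjusted p = 0.00167 and adjusted p = 0.67 with an estimated correlation. The call ended without Opn5-null D, with adjusted p = 0.0679, without both D libraries, with adjusted p = 0.0734, and with fry, with adjusted p = 0.314. The list stood at -1.73 in Opn5-null D. Its median was -0.17 without that library, against -0.53, with 3 genes falling, and 5 fell without Opn5-null C. Aurkb, a mitotic kinase gene, fell by 0.94 on the log2 scale. Replication-dependent histone genes fell in 3 of 8 cases (5 adjusted over the list alone), with camera adjusted p = 0.00973 and adjusted p = 0.48 with an estimated correlation. Without Opn5-null C, 5 histone genes fell. Hist1h1c was 1.68-fold lower. Wnt and Notch signalling genes fell in 9 of 26 cases and rose in 2 (9 and 2 adjusted over the list alone), with camera adjusted p = 0.00611 and adjusted p = 0.49 with an estimated correlation. The list stood at -0.91 in Opn5-null D and between -0.43 and -0.16 in the other Opn5-null libraries, and its median was -0.31 without Opn5-null D, against -0.55. The count that fell was 4 without Opn5-null A and 2, 3, 2 and 3 without wild-type A, B, C and D in turn. Heyl, a Notch target gene, fell by 0.78 and Sp5, a Wnt target gene, rose by 1.77 on the log2 scale.

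Lens markers, which belong to a neighbouring tissue, were lower in the Opn5-null samples. The lens list ranged from -0.91 in wild-type C to 1.01 in wild-type D, as log2 differences from the wild-type mean. It stood at -2.21, -2.19, -1.19 and -1.18 in Opn5-null A, B, C and D. How much lens tissue each sample held was not measured, so a change within the cornea cannot be read from these markers. Of 15 lens markers tested, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.000811 and adjusted p = 0.54 with an estimated correlation. Without Opn5-null A, Opn5-null B, wild-type B and wild-type D in turn, 6 lens markers fell each time. Crybb2 measured 90.8 ± 58.2 against 735 ± 538 normalized counts (SD, n = 4), 8.09-fold lower, and 5.38-fold without wild-type D. Cryba4 was 4.87-fold lower. Conjunctival and goblet cell markers fell in 7 of 10 cases and rose in 0 (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00602 and adjusted p = 0.48 with an estimated correlation. The list stood at -1.89 in Opn5-null D and between -0.98 and -0.62 in the other Opn5-null libraries, and 4, 3 and 4 of its genes fell without wild-type A, B and D in turn. Krt7 was 2.49-fold lower and Clca1 3.29-fold lower. Nerve and Schwann cell markers fell in 6 of 15 cases and rose in 0 (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0171 and adjusted p = 0.48 with an estimated correlation. Without wild-type A and D in turn, 3 of them fell each time. Nefm, a neurofilament gene, was 4.57-fold lower and S100b 3.28-fold lower. That call ended after quantile normalization, upper-quartile scaling and the strict filter, with adjusted p of 0.0587, 0.0559 and 0.0563. Genes known to differ between mouse strains rose in 9 of 16 cases and fell in 1 (10 and 1 adjusted over the list alone), with camera adjusted p = 0.000811 and adjusted p = 0.48 with an estimated correlation. H2-Q7, H2-Q6 and Trim12c were higher by 3.63, 3.51 and 1.69 on the log2 scale, all in families whose reads can be shared. With genes shared between lists left out, that list had adjusted p = 0.0656.

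**Figure D3:**
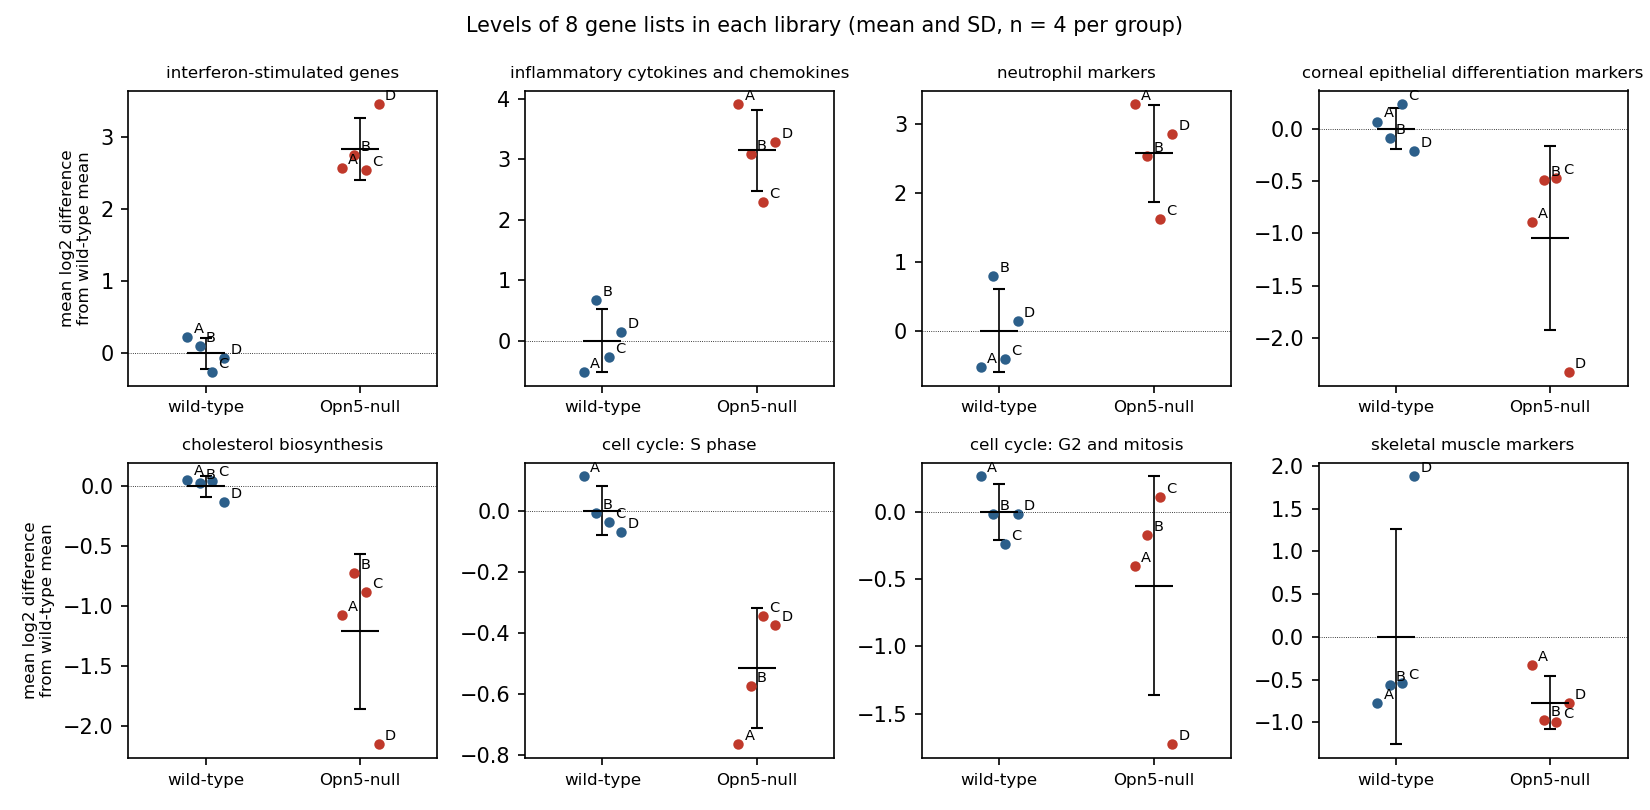
Points are the mean log2 difference of each library from the wild-type mean for 8 gene lists, with the library letter beside each point, and bars are the mean and SD of 4 libraries. Opn5-null D was lowest in the epithelial list at -2.33, and wild-type D was highest in skeletal muscle markers at 1.88.

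Circadian clock genes moved in both directions, with 10 of 22 falling and 4 rising (10 and 4 adjusted over the list alone). The list did not pass as a group (camera adjusted p = 0.0809), but it passed as lower in the edgeR fit (adjusted p = 0.0183), without Opn5-null A (adjusted p = 0.0461) and with fry (adjusted p = 0.00468). Per2 measured 138 ± 18.5 against 487 ± 73.3 normalized counts (SD, n = 4), a log2 fold change of -1.81 ± 0.15 (SE, adjusted p = 0.000124 by limma). Per3 fell by 1.56 and Tef fell by 1.49 on the log2 scale. Nfil3, a repressor of D-box promoters, was 5.65-fold higher. Opsins and light-signalling genes rose in 2 of 14 cases and fell in 2 (2 and 2 adjusted over the list alone, camera adjusted p = 0.745). Plcb2, a phospholipase C gene, was 4.81-fold higher and Plcb3 1.45-fold lower, a call that ended without wild-type A or C (adjusted p of at most 0.0562). Opn3, an opsin gene, had a log2 fold change of 1.19 (adjusted p = 0.0384), and its adjusted p rose to 0.207 at most over the alternatives, 10 of which ended the call.

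**Figure D4:**
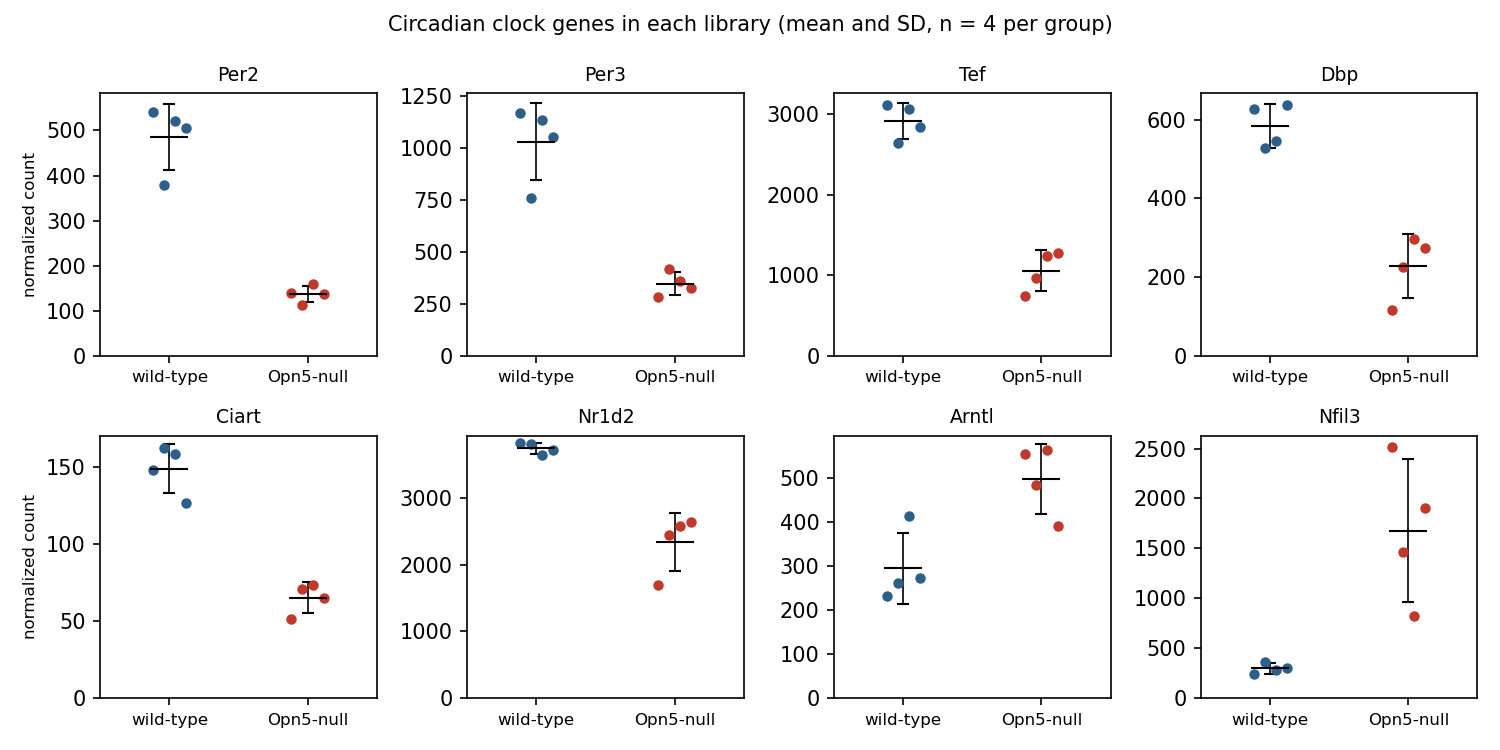
Points are normalized counts in each library for 8 circadian clock genes, and bars are the mean and SD of 4 libraries per genotype. Per2 stood at 138 in Opn5-null and 487 in wild-type corneas on average, and Nfil3 at 1677 and 297.

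The remaining lists did not pass camera with the deposited scaling and all libraries, and some passed under an alternative. TGF-beta and myofibroblast genes rose in 11 of 25 cases and fell in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0512), with Pdgfra 3.05-fold higher. That list passed with upper-quartile scaling (adjusted p = 0.0402), a letter block (0.0455), edgeR (0.0487) and fry (0.0252), and without Opn5-null B (0.0363), Opn5-null C (0.0299) or wild-type B (0.0403). Limbal and basal progenitor markers rose in 3 of 18 cases and fell in 6 (3 and 6 adjusted over the list alone, camera adjusted p = 0.31), with Tfrc 1.89-fold lower and Ifitm3 2.79-fold higher. Oxidative stress genes rose in 9 of 28 cases and fell in 7 (11 and 8 adjusted over the list alone, camera adjusted p = 0.587), with Nqo1 2.54-fold lower and Sod2 4.03-fold higher, and they passed as higher with fry (adjusted p = 0.0365). YAP target genes rose in 5 of 22 cases and fell in 5 (5 and 6 adjusted over the list alone, camera adjusted p = 0.695), with Ankrd1 14.1-fold higher, 25.7-fold without wild-type B, and Ctgf 3.46-fold lower. Nerve growth and axon guidance factors rose in 8 of 26 cases and fell in 3 (8 and 4 adjusted over the list alone, camera adjusted p = 0.544), with Sema4d 2.69-fold higher and Sema3f 1.78-fold lower, and they passed as higher with fry (adjusted p = 0.00853). Keratocyte markers rose in 4 of 18 cases and fell in 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.546), with Angptl7 4.45-fold lower, Thbs4 1.99-fold higher and Col5a1 1.60-fold higher. Corneal endothelium markers fell in 3 of 12 cases (3 adjusted over the list alone, camera adjusted p = 0.108), with Slc4a11 2.61-fold lower. The endothelium list passed without Opn5-null D (adjusted p = 0.0191), without Opn5-null C (0.0496), without both D libraries (0.0188) and with limma-voom (0.00708). Nuclear-encoded oxidative phosphorylation genes fell in 2 of 40 cases (0 adjusted over the list alone, camera adjusted p = 0.365), and cytosolic ribosomal protein genes fell in 2 of 49 (2 adjusted over the list alone, camera adjusted p = 0.697). The latter were Rpl34 and Rplp0, which have near-identical copies. The oxidative phosphorylation list passed as lower with upper-quartile scaling (adjusted p = 0.0387) and the ribosomal list after quantile normalization (adjusted p = 0.0086).

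Markers of vessels, blood and neighbouring tissues also stayed short of the group test with the deposited scaling and all libraries. Blood and lymphatic vessel markers rose in 2 of 17 cases and fell in 1 (2 and 1 adjusted over the list alone, camera adjusted p = 0.587), with Rgs5 2.58-fold lower, Cdh5 1.99-fold higher and Pecam1 1.80-fold higher. Erythrocyte and platelet markers rose in 2 of 7 cases and fell in 2 (2 and 2 adjusted over the list alone, camera adjusted p = 0.529), with Alas2 2.41-fold lower and Pf4 1.92-fold higher, and they passed as higher with fry (adjusted p = 0.0252). Retina, iris and pigment cell markers rose in 1 of 20 cases and fell in 2 (0 and 2 adjusted over the list alone, camera adjusted p = 0.544), with Tyrp1 4.32-fold lower and Rdh5 1.71-fold higher. Skeletal muscle markers fell in 2 of 11 cases (2 adjusted over the list alone, camera adjusted p = 0.094), with Tnni2 1.89-fold lower and a list mean of 1.88 in wild-type D. The muscle list passed without wild-type A (adjusted p = 0.0258). Epidermal and eyelid skin markers rose in 1 of 5 cases and fell in 1 (1 and 2 adjusted over the list alone, camera adjusted p = 0.544), with Tchh 2.75-fold lower and Krt2 higher by 3.98 on the log2 scale. Krt2 had 1 read in the wild-type group, in wild-type A, and a ratio of 101, with a 95% counting interval from 17.6 to 4020. Mitochondrially encoded transcripts rose in 1 of 11 cases (1 adjusted over the list alone, camera adjusted p = 0.108), the gene being mt-Nd2, and they passed as higher without Opn5-null A (adjusted p = 0.0442). Small nuclear and other structured RNAs fell in 1 of 7 cases (1 adjusted over the list alone, camera adjusted p = 0.62), the gene being Neat1. The lacrimal and Harderian gland list and the sex-linked list had 3 and 4 members measured and were not tested as groups. Krt18 was 1.65-fold lower and Ddx3y 1.98-fold higher. The calls of Cdh5, Pecam1, Alas2, Pf4, Rdh5, mt-Nd2, Neat1 and Krt18 ended in 1 or more alternatives, with adjusted p of at most 0.0579, 0.0802, 0.0695, 0.0719, 0.104, 0.163, 0.0731 and 0.0613.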

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

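The tests on strain background, on leukocytes for the cytokine list, on pseudogenes, and on epithelial cells and time of day for the clock genes were chosen after the results were seen. The clock genes with E-box or D-box promoters were also listed after their values were seen. The intervals of differences between medians below resample genes as if they were independent, and leave out the spread between samples. The 35 splits of the 8 libraries into 4 and 4 gave 5204 called genes for the genotypes and at most 0 for any other split. Thus 1 of 35 splits gave as many, the smallest share this test can reach. Every other split mixes the genotypes, which widens the spread within its groups and keeps its count low. The test therefore does not exclude chance beyond that share, and no label gives the samples as separate animals.

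In 27 of 398 groups of 4 samples examined, 6.78%, 1 library lay far from the other 3, and chance flags about 5% of groups. Opn5-null D was far above the others in Cxcl11 at 1158, Cxcl10 at 9327 and Ltbp2 at 1389 normalized counts. It was far below them in Hsd17b7 at 981 and Scn7a at 80.1 normalized counts. The same library lay below in the limbal and basal progenitor list at -0.67 and in the epidermal and eyelid skin list at -0.42, as log2 differences from the wild-type mean. Opn5-null C was far above the others in Sult1a1 at 125, Gm10375 at 0.837, Tfrc at 4611 and Slc4a11 at 4972 normalized counts. Opn5-null B was apart in Myh2 at 2.37. Wild-type D was far above the others in Myh2 at 70.1 and Ltbp2 at 249 normalized counts, and in the skeletal muscle list at 1.88. It was far below them in Insig1 at 3191 and Pmp22 at 1690. Wild-type B was far above in Ifi44l at 0.919, Rps26-ps1 at 139, Mmp10 at 130, Ankrd1 at 271 and Krt18 at 2419, and far below in Fam71f2 at 0 and Psmb9 at 78.1. Wild-type A was far above in H2-T23 at 1446, Krt2 at 1.02 and Rgs5 at 1187. The flagged values of Ifi44l, Gm10375 and Krt2 were 1 read each, and that of Myh2 in Opn5-null B was 2 reads. No reads were found in the other libraries of the group, where any read is flagged, so these values do not set a library apart.

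Lists of inflammatory and interferon-stimulated genes were higher in Opn5-null corneas by camera with a preset correlation, but each had adjusted p = 0.48 with an estimated correlation. Scaling between libraries is argued against, since the lowest median of the interferon-stimulated list over the other scalings was 2.60 and that of the cytokine list 3.23. A larger number of leukocytes cannot be told apart from other sources for either list. All 20 transcripts shared by leukocytes rose. Their median log2 fold change was 2.68, against 2.71 for the interferon list. The interferon median minus the upper quartile of the shared transcripts was -0.24, with a 95% interval of either sign (-1.12 to 0.14). Because an upper quartile is subtracted, lists that rise equally also give a negative value, so the sign does not favour leukocytes. For the cytokine list that difference was 0.44, also with an interval of either sign (-0.55 to 0.89). Among Opn5-null libraries the shared transcripts were highest in A at 3.17 and lowest in C at 1.83, with D at 2.91. The interferon list was highest in D at 3.46 and also lowest in C, at 2.55. In D neutrophil markers stood at 2.85 and monocyte and macrophage markers at 1.44. Dendritic cell and lymphocyte markers were lowest in D at 1.21, close to C at 1.27. Strain background cannot be told apart from genotype, since no label gives it. The list of genes known to differ between strains had a median of 0.67, which does not bear on strain. That list sets no direction for its genes, and it shares H2-K1, H2-D1, H2-Q6 and H2-Q7 with the antigen presentation list. An effect of Opn5 itself stays open beside these sources.

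Of 307 processed pseudogenes tested, 69 were higher and 7 lower in Opn5-null corneas, 22.5% and 2.28%, against 19% and 14.1% of protein-coding genes, and these shares were not compared by a test. Their median lay above that of protein-coding genes by 0.17, with an interval over the pseudogenes, not over samples, from 0.13 to 0.24. For most of the raised ones a segment around Opn5 is argued against, since 4.35% of them lay on chromosome 17 (95% exact interval 0.906% to 12.2%). Of all genes tested on chromosome 17, 33.5% were called, against 32.4% of all genes tested. H2-Q7, H2-Q6, H2-T22, H2-T23, Tap1 and Psmb9, which rose, also lie on chromosome 17, and a segment was not tested for them. Strain background cannot be told apart from genotype, since no label gives it, and the raised pseudogenes lay on 18 chromosomes. Whether reads moved from parents to copies cannot be told apart from other sources: the parents of raised pseudogenes differed in median from the other parents by -0.025 on the log2 scale (one-sided permutation p = 0.145), with 14 called lower and 14 higher.

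The fixed clock list had a median of -0.21, with 10 of 22 genes falling and 4 rising, and a subset of 11 with E-box or D-box promoters, picked after their values were seen, had a median of -0.92. Fewer epithelial cells cannot be told apart: the median of the 11 minus the epithelial median was 0.16 (interval -0.50 to 0.69), and -0.18 without Opn5-null D, with an interval reaching 0.07. The 11 stood at -0.74 in Opn5-null D, where the epithelial list was lowest at -2.33, and between -1.20 and -0.81 in the other Opn5-null libraries, but 1 library does not decide it. Time of day at collection cannot be told apart either, since no label gives it, and Arntl, whose transcript cycles opposite to the genes that fell, had a log2 fold change of 0.78, and an effect of Opn5 on the clock stays open as untested.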

How the results depend on the processing

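The edgeR fit, TMM scaling and the fit without both D libraries were chosen after seeing the data. The count of higher genes was within 1.5 times of 3029 in every alternative except a log2 fold change of at least 1, which gave 1770 higher and 670 lower genes by its stricter threshold. The count of lower genes was 3746 after quantile normalization and 3671 with upper-quartile scaling, while the count of higher genes was 2532 and 2527. These scalings moved the median log2 fold change of all genes from -0.02 to -0.13, which shifts calls from higher to lower. With limma-voom both counts were larger, 3938 higher and 3526 lower, and the cause was not tested. Leaving out 1 library gave from 2225 to 3365 higher and from 1078 to 2540 lower genes. It gave from 13 to 14 lists higher and from 9 to 10 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, against 13 and 9. Estimated correlations reached 0.95, against the preset 0.01. For the clock list, at 0.0125, the unadjusted camera p still rose from 0.0485 to 0.10, and the cause was not tested. A replicate block by letter gave 2545 higher and 1691 lower genes. No label says that the letters pair the samples. Deviations of same-letter libraries correlated at -0.16, -0.13, 0.14 and 0.13, which shows no strong shared deviation. Libraries of different letters were not set beside them, so a pairing was not tested. Of 158 named genes, 137 kept direction and call in every alternative fit that tested them and 21 lost the call in at least 1, while 0 reversed. The 21 were Alas2, Bpgm, Cdh5, Cry2, Gja1, Hist1h1d, Hist1h2bc, Krt18, mt-Nd2, Myh2, Ndufv1, Neat1, Nkd1, Notch2, Opn3, Pecam1, Pf4, Plcb3, Rdh5, Scn7a and Sdha. The other thresholds were applied to the counts of genes, and 39 called named genes had an absolute log2 fold change below 1. The fold change of Opn5 was not analysed here under any setting. DESeq2 was not run for the gene lists. At this depth a gene with 0 reads is known only to lie under 3 reads per group.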

Other observations

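Gene types were counted without a test between them, and no label gives the strain of either genotype. Of 14 polymorphic pseudogenes tested, 8 were higher and 0 lower in Opn5-null corneas, and of 14 mitochondrial transfer RNA genes 8 were higher and 0 lower. Among protein-coding genes, 2700 were higher and 2003 lower of 14190. Gbp2b, a guanylate-binding protein gene chosen after its values were seen, measured 73.7 ± 17.9 normalized counts in Opn5-null and 0.701 ± 1.40 in wild-type corneas (SD, n = 4), where its reads were in wild-type D alone. Rps3a1 fell by 0.76 on the log2 scale while its copy Rps3a2 was higher by 3.25, and with both copies added the family stood at -0.35. Pcna stood at -0.48 with its copy added, against -0.73 alone. Ribosomal genes Rplp0 and Rpl34, with their copies added, stood at -0.24 and -0.60 on the log2 scale, against -0.46 and -0.83 alone.

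Further clock genes, chosen after their values were seen, also differed between the genotypes. Dbp had a log2 fold change of -1.43 and Ciart of -1.19, while Bhlhe40 was higher by 1.27. Per1 had a log2 fold change of 0.25 and did not pass the test (adjusted p = 0.521 by limma).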
